A study of Mus musculus with 9 samples.

How the data were processed

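Gene expression was measured on 1-colour arrays with 9 RNA samples in 3 groups of 3. The groups were R1 mouse embryonic stem (ES) cells, labelled strain 129S6, mouse embryonic fibroblasts (MEF), labelled C57BL/6J, and induced pluripotent stem (iPS) clones made from C57BL/6J embryonic fibroblasts with a lentiviral vector carrying the microRNA cluster of miR-302 and miR-367. ES arrays carry the numbers 4, 5 and 6, MEF arrays 1, 2 and 3, and the iPS arrays the clone numbers 6, 7 and 10. Per the labels' protocols, total RNA was extracted with Trizol and prepared for the arrays with the Ambion WT Expression Kit with a biotin label. The labels' growth protocol names samples 4, 5 and 6 as kept in fibroblast medium and harvested with trypsin, and the others as kept in mouse ES medium with feeder cells eliminated before harvest. Which numbering that protocol means is not stated. By title these numbers are ES arrays, and the feeder step would then cover MEF and iPS. By listing order they are MEF arrays, so that fibroblast medium goes to fibroblasts and the feeder step covers ES and iPS. The listing order pairs each cell type with its medium and is the likelier reading, but the labels do not state it. No comparison rests on the numbering, but whether feeders were eliminated from the ES samples does.

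The values analysed are the authors' processed values, 1 per probe set and array. Their scale is not stated in the labels: the deposited values were read as log2 from the values themselves, which ran from 3.08 to 14.24 with none missing. Partek 6.5 is named per the submitters' processing notes, with no role given, and the background correction, normalization and summarization are not given in the sources used here. The array medians were 7.44, 7.41 and 7.39 for ES 4, 5 and 6, 7.31, 7.38 and 7.40 for MEF 1, 2 and 3, and 7.46, 7.37 and 7.38 for iPS clones 6, 7 and 10. Exactly equal values in all 3 arrays of a group were held by 368 probe sets in ES, 135 in MEF and 129 in iPS, so the SD of a group can be 0. No further normalization was applied. The number of arrays limits the precision.

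Of the 28270 probe sets, 21780 carried 1 gene symbol, 1617 carried several and 4873 carried none in the annotation used. Gene IDs matched 21689 of the probe sets with 1 symbol to the reference gene table of assembly GRCm38.p6, and 0 symbols changed by that match. The array's own genome build is not named, so the reference served only for names, chromosomes and gene order. Each of 19934 genes was represented by the probe set with the highest mean over all 9 arrays, a choice that mattered for 996 genes with more than 1 probe set. Probe sets with several symbols or none were left out, except in the alternative that counted every probe set.

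Differences between groups were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all 9 arrays, 1 mean per group and a spread shared by the groups (prior degrees of freedom 3.11). Benjamini-Hochberg adjustment ran over all 19934 genes within each of the 3 comparisons (iPS vs MEF, iPS vs ES and ES vs MEF), and a gene passed at an adjusted p under 0.05. SE is the standard error of the fitted difference, and n = 3 arrays in each group. An exact permutation test of 3 arrays against 3 cannot give a p under 0.1. Whether the ES and MEF arrays came from separate cultures or animals is not stated, so the p-values measure only the spread between these samples, which may be technical. Strain is known only from the labels, which give MEF and iPS the same strain and ES another, so by the labels strain and cell origin cannot be separated in any comparison with ES. The labels give no batch.

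Before the data were examined, 27 gene lists were fixed, along with the tests, the alternatives and the rule for naming genes. They cover the locus of miR-302 and miR-367, core and naive pluripotency, primed pluripotency, fibroblast and mesenchymal genes, factors of the epithelial-to-mesenchymal transition (EMT) with TGF-beta signalling, epithelial junctions, reported miR-302 family targets, the imprinted Dlk1-Dio3 region, other imprinted genes, senescence and p53, cell cycle, DNA methylation and Polycomb, neuroectoderm, mesoderm, endoderm, trophectoderm, germ line, the 2-cell-like state, Hox genes, glycolysis, the interferon response, macrophages, endothelium, muscle, keratinocytes, sex-linked genes and genes that differ between the 129 and C57BL/6J strains. Members were counted by direction over all genes tested and adjusted over the list alone. Each list was set against all other genes with camera at its preset correlation of 0.01, and again with an estimated correlation. The limma function fry tested whether a list's genes moved one way on balance. List p-values were adjusted over the 27 lists within a comparison. List genes whose symbol no probe set of the values analysed carried alone were not analysed here, unless a synonym matched. In the imprinted list such a match put another gene, Nckap1, in place of H19. In the glycolysis list it put Pigq in place of Gpi1. The counts and tests of these lists therefore include a gene that was not meant. The number of measured genes is given with each list.

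Named genes are, for each comparison, the 10 largest rises and the 10 largest falls among genes past the test whose arrays did not overlap between the groups, the list members with the largest absolute change, past the test or not, and all 6 members of the list for that microRNA locus. Symbols that are only clone or model names (such as those ending in Rik or starting with Gm or AI), olfactory receptors, and probe sets of several genes were excepted. Other genes are named only as said, as chosen after their values were seen. Zfp980 and Zfp640 belong to a zinc finger family with near-identical members, so their probe sets may read related genes.

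The position of each clone between MEF and ES was its projection, after subtracting the MEF mean, on the line from the MEF mean to the ES mean over all genes. The correlation of the iPS and ES changes from MEF was set beside 100 simulations of unchanged groups that share the same MEF arrays. Spread within a group was the median over genes of the SD of its 3 arrays.

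The procedure was tested on simulated data of 19934 genes with each group's own spread. For iPS vs ES it called 65.7% of genes changed 1.5-fold, 80.6% of genes changed 2-fold and 98.5% of genes changed 4-fold, with 192 false calls. For iPS vs MEF the shares were 68.7%, 88.1% and 95.5%, with 178 false calls. With an equal spread in all groups, false calls fell to 7 for iPS vs ES and 12 for iPS vs MEF. With no change simulated, 20 simulations at each group's own spread gave a median of 68 false calls for iPS vs ES (highest 94), 80.5 for iPS vs MEF (highest 124) and 0 for ES vs MEF (highest 1).

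Alternatives to 1 choice at a time were quantile normalization of the values again, centring each array on its median, leaving out the dimmest genes (1 in 3), the mean of a gene's probe sets, every probe set, only the 2 groups compared, an intensity trend with robust moderation, array weights, no moderation, a 2-fold minimum, an adjusted p under 0.01, camera with an estimated correlation, fry, and leaving out each array in turn. Chosen after seeing the data were a fit that uses the spread of the clones alone for both groups compared, and 1 array weight per group. In all, 24 settings besides the reported one were tried. Computations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.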

Results

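Fibroblasts can be turned into pluripotent cells by forced expression of the microRNA cluster that holds miR-302 and miR-367. Here 3 iPS clones made in this way were compared with MEF, the cell type they came from, and with ES cells, each group with n = 3 arrays. Changes are log2 differences of group means with the SE and adjusted p of limma. After the counts of a list, an adjusted p is that of the list against other genes.

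The clones expressed pluripotency genes, and fibroblast genes were lower than in MEF. The transcription factors Pou5f1, Sox2 and Nanog form the core circuit of pluripotency, Nr0b1 acts beside them, Tdgf1 is a co-receptor of Nodal, and Utf1 and Dppa5a mark undifferentiated cells. All of these rose strongly from MEF to iPS. Nr0b1 rose most (log2 6.99, SE 0.158, adjusted p = 3.23e-09), followed by the peptide ligand gene Apela (6.57, SE 0.286, adjusted p = 1.15e-07), Tdgf1 (6.46, SE 0.155, adjusted p = 4.17e-09) and Pou5f1 (6.46, SE 0.192, adjusted p = 1.26e-08). Zfp980 (6.29), Dppa5a (6.14), Utf1 (5.95), the brain-expressed X-linked gene Bex1 (5.91), Sox2 (5.73) and Zfp640 (5.68) completed the 10 largest rises. Nanog rose by 5.20 (SE 0.111, adjusted p = 2.5e-09). Of 37 core and naive pluripotency genes, 35 were higher and 0 lower (36 and 0 adjusted over the list alone), and the list stood above other genes (adjusted p = 8.29e-23). Of 15 genes of primed pluripotency, a later epiblast-like state, 11 were higher, among them Zic5 (3.62), Zic2 (3.44) and Lefty1 (2.70), and 1 was lower, the activin antagonist Fst (−2.70), with 12 and 1 adjusted over the list alone and 2 lower without clone 6. That list passed against other genes (adjusted p = 0.000114) but not with an estimated correlation (adjusted p = 0.0834 with an estimated correlation).

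Genes that build and contract the fibroblast's surroundings fell, and most of those that hold epithelial cells together rose. Lox crosslinks collagen, Acta2, Actg2 and Tagln encode contractile proteins, Snai2 and Twist2 repress epithelial genes, and Tgfb3 encodes a TGF-beta ligand that favours the mesenchymal state. Cdh1 and Epcam encode adhesion proteins of epithelial cells, Cldn6 a tight junction protein and Esrp1 a splicing regulator of epithelia. The largest fall was that of Lox (−5.40, SE 0.2, adjusted p = 4.28e-08), then the muscle-stress gene Ankrd1 (−5.32, SE 0.0949, adjusted p = 2.02e-09), Actg2 (−5.27), Tgfb3 (−5.10, SE 0.0769, adjusted p = 1.53e-09), Anxa3 (−5.07), P2ry10b (−4.98), Cavin2 (−4.95), Col12a1 (−4.95), Pla2g4a (−4.90) and Anxa1 (−4.87). All 36 fibroblast and mesenchymal genes were lower, with 36 also adjusted over the list alone (adjusted p = 1.08e-22). Of 15 EMT and TGF-beta genes, 14 were lower and 0 higher, the same adjusted over the list alone (adjusted p = 3.55e-11), with Snai2 at −3.46, Twist2 at −3.00 and Tgfb2 at −2.93. Of 23 epithelial junction genes, 18 were higher, led by Cdh1 (4.69, SE 0.119, adjusted p = 6.14e-09), Epcam (4.65), Cldn6 (3.59) and Esrp1 (3.25). The 1 lower was the desmosome gene Pkp2 (−0.72, adjusted p = 0.0148), chosen after its value was seen, and 0 were lower without MEF 1; adjusted over the list alone the counts were 19 and 1. The epithelial list stood above other genes (adjusted p = 1.37e-09), a call that was lost with an estimated correlation (adjusted p = 0.108 with an estimated correlation).

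Precursors of the reprogramming microRNAs read low on these arrays in every group. The cluster lies in an intron of Larp7, whose message rose by 0.56 (SE 0.123, adjusted p = 0.00456). The precursor features of the cluster stayed between log2 3.7 and 4.8 in all group means, near the low end of the values. They read low in ES as well, so they cannot show whether the mature microRNAs were present or raised in the clones. From MEF to iPS, Mir302b differed by 0.28 (adjusted p = 0.106), Mir302a by 0.12 (adjusted p = 0.499), Mir302c by 0.12 (adjusted p = 0.679), Mir302d by 0.11 (adjusted p = 0.614) and Mir367 by 0.06 (adjusted p = 0.498). Thus 1 of 6 members of the locus list was higher and 0 lower, the same adjusted over the list alone (adjusted p = 0.36), with 3 higher without clone 7 and 2 without clone 10. Among 21 reported targets of the miR-302 family, 13 were lower and 6 higher (14 and 7 adjusted over the list alone). The lower ones included the apoptosis protease Casp8 (−3.74, adjusted p = 5.36e-08), the Hippo kinase Lats2 (−3.04, adjusted p = 5.45e-07) and the interferon regulator Irf2 (−2.81, adjusted p = 1.39e-08), and the Nodal antagonist Lefty1 was higher (2.70). The target list lay below other genes (adjusted p = 0.00988; adjusted p = 0.0834 with an estimated correlation).

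Most cell division, chromatin and germ line genes rose, and most Hox genes, which mark position along the body, fell. Mycn drives growth, Bub1b and Cdca7 serve mitosis and replication, Uhrf1 recruits the maintenance methylase, Dnmt3l and Dnmt3b establish DNA methylation and Tet1 removes it. Of 29 cell cycle genes 27 were higher and 0 lower, also adjusted over the list alone, with Mycn at 3.13, Bub1b at 2.91, Cdca7 at 2.91 and Uhrf1 at 2.57 (list adjusted p = 6.83e-15; adjusted p = 0.088 with an estimated correlation). Of 23 DNA methylation and Polycomb genes 18 were higher, led by Dnmt3l (4.94), Tet1, Dnmt3b (3.32) and Cbx7 (3.26). The 2 lower ones, chosen after their values were seen, were Mbd2 (−2.10) and Tet3 (−0.40), and 1 was lower without MEF 1, MEF 3 or clone 10; the counts were the same adjusted over the list alone (adjusted p = 1.37e-07). Of 17 germ line genes 14 were higher and 0 lower (17 and 0 adjusted over the list alone), among them Mael (3.64), which guards against transposons, and the meiotic genes Sycp3 (2.90) and Dazl (2.86), with an adjusted p = 6.82e-07 for the list. Of 33 Hox genes 29 were lower and 0 higher (30 and 0 adjusted over the list alone; 1 higher without clone 10), with Hoxc8 at −3.88, Hoxc6 at −2.86, Hoxc5 at −2.65 and Hoxa5 at −2.28 (list adjusted p = 7.33e-13; adjusted p = 0.0957 with an estimated correlation). Of 19 genes measured for the glycolysis list, Pigq among them in place of Gpi1, 8 were higher and 0 lower. The counts were 9 and 0 adjusted over the list alone, and 3 were lower without clone 7. The glucose transporter Slc2a3 stood at 4.90, Pdk1 at 3.11, Aldoc at 2.48 and the lactate transporter Slc16a1 at 2.42. Against other genes the list had an adjusted p = 0.00269, and an adjusted p = 0.432 with an estimated correlation.

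Imprinted and growth arrest genes moved in both directions, and 4 of 5 strain markers fell. The growth inhibitor Phlda2 rose (4.65, adjusted p = 2.21e-07), the growth factor Igf2 (−3.04, adjusted p = 5.03e-06) and the receptor adaptor Grb10 (−3.34, adjusted p = 2.09e-07) fell, and Mest rose (2.98, adjusted p = 5.36e-07). Of 22 genes measured for the list of imprinted genes outside the Dlk1-Dio3 region, 6 were higher and 10 lower (adjusted p = 0.203). Adjusted over the list alone the counts were 6 and 11. These 22 include Nckap1, which was read in place of H19. In the Dlk1-Dio3 region, 1 of 5 genes was lower and 0 higher, also adjusted over the list alone (adjusted p = 0.258). That gene was Dlk1 (−2.36, SE 0.0818, adjusted p = 3.01e-08), while the non-coding Meg3 stood at −1.22 (SE 0.5, adjusted p = 0.0802). Without clone 7 Meg3 stood at −0.47 (adjusted p = 0.000149), without clone 6 at −1.60 (adjusted p = 0.0352) and without clone 10 at −1.59 (adjusted p = 0.0405). Without MEF 3 there was 1 higher, and without clone 6, 7 or 10 there were 2 lower. Of 17 senescence and p53 genes 10 were lower and 2 higher, also adjusted over the list alone (adjusted p = 0.0928), with Plk2 at −2.37, Perp at −1.98, the cell cycle inhibitor Cdkn2b at −1.90 and Il6 at −1.60. The 2 higher, Gadd45a (1.31) and Sesn2 (0.63), were chosen after their values were seen, and 4 were higher without clone 7. Of 5 strain markers 4 were lower and 0 higher, also adjusted over the list alone: Ifi202b (−1.26), Nnt (−1.02), Wdfy1 (−0.92) and Entpd4 (−0.86), with an adjusted p = 0.0146 for the list (adjusted p = 0.0957 with an estimated correlation), although both groups carry the same strain label.

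Lineage, vessel, immune and muscle genes moved in both directions. Members named in this paragraph only to complete a count were chosen after their values were seen (Neurod1, Tubb3, Sox1, Zic1, Kdr, Sox7, Gata4, Cubn, Plac1, Csf1r, Emcn, Vwf, Chrna1 and Bst2). Of 12 neuroectoderm genes 5 were higher (Olig2 1.63, Pax6 1.42, Neurod1, Tubb3 and Sox1) and 3 lower (Nes −3.17, Map2 −1.94 and Zic1), with an adjusted p = 0.617 for the list. Of 13 mesoderm genes Eomes was higher (0.65) and 4 were lower (Gata2 −0.76, Foxf1 −0.57, Hand2 −0.55 and Kdr; adjusted p = 0.66), with 2 higher without MEF 3. Of 15 endoderm genes 3 were higher (Lama1 2.87, Sox7 and Gata4) and 4 lower (Dab2 −3.02, Pdgfra −1.64, Col4a1 −1.51 and Cubn; adjusted p = 0.739). Of 11 trophectoderm genes 2 were higher (Tfap2c 2.58 and Plac1) and 2 lower (Gata3 −0.93 and Krt7 −0.71; adjusted p = 0.728), with 1 and 2 adjusted over the list alone and 1 higher without ES 4, 5 or 6 or MEF 1 or 3. Of 4 measured 2-cell-like genes 3 were higher and 0 lower: Tdpoz3 (1.12), Zfp352 (0.57, adjusted p = 0.0184) and Tcstv3 (0.42, adjusted p = 0.0184), with an adjusted p = 0.131 for the list. Without MEF 1 or clone 6 only 1 of them was higher, Tcstv3 then reaching an adjusted p = 0.057 without MEF 1. Of 23 interferon genes 7 were lower (Ifit2 −1.61, B2m −1.42, Ifi35 −1.23 and Tap1 −0.98 among them) and Bst2 was higher (adjusted p = 0.129), with 2 higher without MEF 3 or without any 1 of the clones. Of 14 macrophage genes 2 were higher (Laptm5 3.68 and Cd68 0.91) and 3 lower (Lyz2 −1.05, Cd14 −0.74 and Csf1r; adjusted p = 0.895). Of 13 endothelial genes 4 were higher (Egfl7 0.95, Tek 0.89, Esam 0.58 and Vwf) and 2 lower (Flt1 −2.76 and Emcn; adjusted p = 0.447), Egfl7 with an adjusted p = 0.0636 without MEF 1. Of 14 muscle genes Myl4 was higher (0.83) and 4 were lower (Des −1.14, Tnnt2 −0.72, Tnnc1 −0.69 and Chrna1; adjusted p = 0.65), with 2 higher without clone 10. Of 11 keratinocyte genes 2 were higher (Sfn 2.61 and Krt17 0.80) and Perp was lower (−1.98; adjusted p = 0.617). Of 4 sex-linked genes Xist, the RNA that coats the inactive X chromosome, was lower (−4.12, adjusted p = 1.75e-06) and 0 were higher (adjusted p = 0.258), with 2 higher without clone 10 and 2 lower without clone 6. Apart from trophectoderm, the counts in this paragraph were the same adjusted over the list alone. The neuroectoderm, mesoderm, endoderm, macrophage and muscle lists differed in sign between median, mean and test.

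In all, 8488 of 19934 genes (42.6%) passed between iPS and MEF, 3954 higher and 4534 lower, and 3416 of them changed at least 2-fold (1319 higher, 2097 lower). With the spread of the clones alone, a fit chosen after the data were seen, 4020 passed (1477 higher, 2543 lower). The arrays of the groups did not overlap for 47.7% of genes, where 10% would be expected by chance if both groups had the same spread. Of the 27 lists 12 passed against other genes and 5 of these also with an estimated correlation: pluripotency, fibroblast, EMT, DNA methylation and germ line genes, the largest of those 5 values being an adjusted p = 0.0394 for the fibroblast list. The test named fry asks whether the genes of a set move on balance one way and does not compare them with other genes.

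The clones nonetheless differed from ES cells. Zfp42 is a marker of naive pluripotency, Triml2 lies beside it, Klf2 supports the naive state and Foxd3 guards against early differentiation. All 4 were lower in iPS than in ES. Zfp42 fell by 2.17 (SE 0.179, adjusted p = 0.000498) and Triml2 by 2.15 (SE 0.108, adjusted p = 3.1e-05), both still far above MEF, since Zfp42 stood at log2 11.07 in ES, 8.89 in iPS and 5.95 in MEF. The other largest falls were those of the immune ligand gene H60b (−2.44, SE 0.185, adjusted p = 0.000364), Nlrp9b (−2.25, SE 0.0851, adjusted p = 1.27e-05), Accsl (−2.21), the neural factor Neurod1 (−2.13, SE 0.197, adjusted p = 0.000721), the membrane repair gene Myof (−2.06), Hunk (−2.00), Muc3 (−1.97) and Spic (−1.95). The largest rises were Elobl (1.81, SE 0.202, adjusted p = 0.00144), the bacterial sensor Nod1 (1.77, SE 0.285, adjusted p = 0.00845), the clock-linked repressor Bhlhe40 (1.62, SE 0.112, adjusted p = 0.000196), the ribosomal gene Rpl34 (1.55), the glial factor Olig2 (1.52), Gipc2 (1.51), Maff (1.51), the fatty acid carrier Fabp3 (1.49, SE 0.0854, adjusted p = 6.45e-05), Galnt6 (1.48, SE 0.338, adjusted p = 0.0382) and Prelid2 (1.41). Of these 20, Nod1 missed the threshold without ES 5 (adjusted p = 0.0504) and Galnt6 without ES 4, 5 or 6 (adjusted p = 0.13 to 0.15) and in other settings. With the spread of the clones alone in limma, 0 of the 20 passed, nor did any other gene between iPS and ES (lowest adjusted p = 0.386).

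Most pluripotency genes stood near their ES level. Of the 37, 3 were lower and 0 higher: Zfp42, Klf2 (−0.90, SE 0.172, adjusted p = 0.0184) and Fbxo15 (−0.63, SE 0.111, adjusted p = 0.0133), while Nanog (−0.40, adjusted p = 0.0814) and Gdf3 (−0.51, adjusted p = 0.0566) missed the test. Adjusted over the list alone 6 were lower and 0 higher. Only 1 was lower without ES 4, 5 or 6, where Klf2 reached an adjusted p = 0.0828, 0.0663 and 0.0897 and Fbxo15 an adjusted p = 0.0577, 0.0604 and 0.0782 in turn. Without clone 7 there were 11 lower, and without clone 6 there were 2 higher. The list lay just below other genes (adjusted p = 0.0496), but not with an estimated correlation (adjusted p = 0.884 with an estimated correlation), and fry gave an adjusted p = 0.204. Of the primed genes 1 was lower, Foxd3 (−1.15, SE 0.171, adjusted p = 0.00554), and 1 higher, Zic2 (0.63, adjusted p = 0.0282), with 2 and 2 adjusted over the list alone (adjusted p = 0.941). Zic2 was lost without ES 4, 5 or 6, MEF 2 or clone 6 (0 higher), the value without ES 4 being an adjusted p = 0.105; 3 were higher and 4 lower without clone 7, and 2 lower without clone 6.

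A part of the fibroblast genes was lower in the clones than in ES cells. Cdh11 and Cav1 encode a mesenchymal cadherin and the coat protein of caveolae, Prrx1 is a limb mesenchyme factor, and Timp2 and Fbln2 act in the matrix. Of 36 fibroblast genes 13 were lower and 0 higher (18 and 0 adjusted over the list alone; 2 higher without clone 7). The largest differences among those 13 were Cdh11 (−1.41, SE 0.167, adjusted p = 0.00189), Lox (−1.40, SE 0.2, adjusted p = 0.00446), Cav1 (−1.40, SE 0.164, adjusted p = 0.00178), Prrx1 (−1.31, SE 0.147, adjusted p = 0.00151), Acta2 (−1.28, SE 0.125, adjusted p = 0.000805), Timp2 (−1.18) and Fbln2 (−1.08). Timp3 (−1.24, adjusted p = 0.0666) missed the test. The list lay below other genes (adjusted p = 1.03e-12; adjusted p = 0.272 with an estimated correlation). Of 15 EMT and TGF-beta genes 7 were lower and 0 higher (8 and 0 adjusted over the list alone), with Tgfbi at −0.97 (SE 0.0851, adjusted p = 0.000645), Snai2 at −0.64 (adjusted p = 0.00711), Tgfb1 at −0.58 (adjusted p = 0.0484) and Snai1 at −0.53 (adjusted p = 0.0102). Without ES 4, 5 or 6 the lower ones numbered 3, 2 and 3, Snai1 reaching an adjusted p = 0.0556, 0.0589 and 0.0548, Tgfb1 an adjusted p = 0.167, 0.128 and 0.195, and Snai2 an adjusted p = 0.0501 without ES 5; without clone 7 there was 1 higher. Tgfb1 was also lost after quantile normalization (adjusted p = 0.0605). The EMT list passed (adjusted p = 1.15e-05; adjusted p = 0.0915 with an estimated correlation).

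A few epithelial genes were lower in iPS than in ES. Grhl2 is a master factor of epithelia and Rab25 a trafficking protein of epithelial cells. Of 23 genes 4 were lower and 0 higher: Grhl2 (−0.90, SE 0.118, adjusted p = 0.00293), Rab25 (−0.87, SE 0.141, adjusted p = 0.00883), Pkp2 (−0.81, SE 0.198, adjusted p = 0.0498) and, chosen after its value was seen, Cdh1 (−0.52, SE 0.119, adjusted p = 0.039). Adjusted over the list alone 1 was higher and 5 lower, and the list did not differ from other genes (adjusted p = 0.941). Lower genes numbered 1, 2 and 1 without ES 4, 5 and 6 and 2 without MEF 1, MEF 2, MEF 3 or clone 10. Rab25 then had an adjusted p = 0.0506 without ES 4 and 0.0526 without ES 6, and Pkp2 an adjusted p = 0.142 without ES 4, 0.186 without ES 5 and 0.176 without ES 6. There was 1 higher without clone 10, 1 without clone 6 and 2 without clone 7. Pkp2 also missed after quantile normalization (adjusted p = 0.0537).

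Reported miR-302 targets and imprinted genes held a few further differences. Of 21 targets 3 were lower and 0 higher: Casp8 (−1.10, SE 0.144, adjusted p = 0.00298), the cyclin Ccnd1 (−0.83, SE 0.163, adjusted p = 0.0208) and the TGF-beta receptor Tgfbr2 (−0.47, SE 0.1, adjusted p = 0.0289), with 4 and 0 adjusted over the list alone (adjusted p = 0.0539 for the list). Only 1 stayed lower without ES 4, 5 or 6, where Ccnd1 reached an adjusted p = 0.0828, 0.0933 and 0.0951 and Tgfbr2 an adjusted p = 0.104, 0.14 and 0.113; 1 was higher without clone 6 or 7. Of the microRNA locus list 0 of 6 passed, also adjusted over the list alone (Mir302b 0.24, adjusted p = 0.37; Larp7 −0.19, adjusted p = 0.499; Mir302d 0.06, Mir302c 0.05, Mir367 0.02 and Mir302a 0.00), with an adjusted p = 0.885 for the list. Of 22 genes of the imprinted list 3 were lower and 0 higher: Grb10 (−1.60, SE 0.159, adjusted p = 0.000865), the amino acid transporter Slc38a4 (−0.76, SE 0.0821, adjusted p = 0.00134) and, chosen after its value was seen, Cdkn1c (−0.62, adjusted p = 0.00714). Nckap1, which stood in that list for H19, did not pass (adjusted p = 0.674). Adjusted over the list alone 2 were higher and 3 lower (adjusted p = 0.885), with 1 higher without clone 10, 2 without clone 6 and 7 without clone 7, and 6 lower without clone 6. In the Dlk1-Dio3 region 0 of 5 passed, also adjusted over the list alone, with Meg3 at −0.77 (SE 0.5, adjusted p = 0.488), Rian at −0.55 (adjusted p = 0.607) and Dlk1 at 0.08 (adjusted p = 0.714), and an adjusted p = 0.623 for the list. Clone 7 alone carried the first 2 differences, since without it Meg3 stood at −0.02 (adjusted p = 0.858) and Rian at 0.11, neither past the test.

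Glycolysis was the 1 list that stood above other genes in iPS against ES (adjusted p = 6.78e-06). The call was lost with an estimated correlation (adjusted p = 0.645 with an estimated correlation), and fry gave an adjusted p = 0.0848. Aldoc and Pgk1 encode glycolytic enzymes and Slc2a3 imports glucose. The 19 genes measured included Pigq in place of Gpi1, and Pigq did not pass (adjusted p = 0.935). Of the 19, 3 were higher and 0 lower (5 and 0 adjusted over the list alone): Aldoc (0.88, SE 0.192, adjusted p = 0.0326) and, chosen after their values were seen, Pgk1 (0.50, SE 0.0741, adjusted p = 0.00547) and Slc2a3 (0.42, SE 0.0907, adjusted p = 0.0312). Only 1 was higher without ES 4, 5 or 6, where Aldoc had an adjusted p = 0.116, 0.139 and 0.121, while 5 were higher without clone 10 or clone 7 and 1 was lower without clone 6.

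Germ line, neural and proliferation genes differed singly. Among 17 germ line genes Stra8, which starts meiosis, was higher (1.13, adjusted p = 0.0198), and 4 were lower: Tdrd12 (−1.41, SE 0.104, adjusted p = 0.000308), Rhox9 (−0.88, adjusted p = 0.0333), Prdm1 (−0.77, adjusted p = 0.0133) and, chosen after its value was seen, Stk31 (−0.62, adjusted p = 0.0177), with 3 and 6 adjusted over the list alone (adjusted p = 0.623). Without ES 4, 5 or 6, 0 were higher and 2, 1 and 1 were lower, Stra8 then having an adjusted p = 0.0806, 0.0889 and 0.0908, Rhox9 an adjusted p = 0.13, 0.119 and 0.131, and Prdm1 an adjusted p = 0.0522, 0.075 and 0.0689; 3 were higher without clone 6 or 7. Among 12 neuroectoderm genes Olig2 and Sox11 (0.79, adjusted p = 0.0401) were higher and Neurod1 and, chosen after its value was seen, Tubb3 (−0.79, adjusted p = 0.0144) were lower, with 3 and 3 adjusted over the list alone (adjusted p = 0.885). Without any 1 of the ES or MEF arrays or clone 6 only 1 was higher, Sox11 having an adjusted p = 0.162 without ES 4, and without any 1 of the ES arrays only 1 was lower. Of 29 cell cycle genes Mycn was lower (−0.79, SE 0.0951, adjusted p = 0.00204) and 0 higher, also adjusted over the list alone (adjusted p = 0.229), with 1 higher and 3 lower without clone 6 and 11 lower without clone 7. Of 23 DNA methylation and Polycomb genes Jarid2 was lower (−0.32, adjusted p = 0.0495) and 0 higher, with 0 and 0 adjusted over the list alone (adjusted p = 0.772). It was lost without ES 4, 5 or 6, MEF 2 or clone 6 (0 lower; adjusted p = 0.154 without ES 4), and 3 were lower without clone 7. Of 33 Hox genes Hoxc8 (−0.98, SE 0.0705, adjusted p = 0.000265) and Hoxc6 (−0.31, adjusted p = 0.0465) were lower and 0 higher, also adjusted over the list alone (adjusted p = 0.772). Hoxc6 was lost (1 lower) without ES 4, 5 or 6, MEF 2, MEF 3 or clone 10, with an adjusted p = 0.158 without ES 4, and 4 were lower without clone 6.

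Remaining lists held at most 1 call in a direction. Cdkn2b (−0.41, adjusted p = 0.0128) was the 1 senescence gene lower, with 0 higher, also adjusted over the list alone (adjusted p = 0.885), and it was lost without ES 4, 5 or 6 (0 lower; adjusted p = 0.0713, 0.078 and 0.0559), while clone 7 left out gave 4 higher and 3 lower. Pdgfra (−0.65, SE 0.087, adjusted p = 0.00334) was the 1 endoderm gene lower and 0 were higher (1 and 1 adjusted over the list alone; adjusted p = 0.741), with 2 higher without clone 10 or 7. Among interferon genes B2m, a subunit of major histocompatibility complex class I, was higher (0.65, adjusted p = 0.0405) and 0 lower, also adjusted over the list alone (adjusted p = 0.885); it was lost (0 higher) without ES 4, 5 or 6, MEF 2, MEF 3, clone 10 or clone 6, with an adjusted p = 0.162 without ES 4, and 5 were lower without clone 7. Among endothelial genes Esam was lower (−0.51, adjusted p = 0.0308) and 0 higher, also adjusted over the list alone (adjusted p = 0.941). Esam was lost (0 lower) without ES 4, 5 or 6, MEF 2, clone 10 or clone 6, with an adjusted p = 0.15 without ES 5; 2 were lower without clone 7 and 1 higher without clone 6. Among muscle genes Myl4 was higher (0.86, adjusted p = 0.0378) and 0 lower, also adjusted over the list alone (adjusted p = 0.885); it was lost (0 higher) without any 1 of the ES or MEF arrays or clone 10, with an adjusted p = 0.171 without ES 5, and 1 was lower without clone 7. Among keratinocyte genes Krt17 was lower (−0.98, adjusted p = 0.0255) and 0 higher, also adjusted over the list alone (adjusted p = 0.941); it was lost (0 lower) without ES 4, 5 or 6 or MEF 2 (adjusted p = 0.105, 0.0877, 0.114 and 0.0552), and 1 was higher and 2 lower without clone 7. Of 5 strain markers Nnt was higher (0.59, SE 0.0814, adjusted p = 0.00358) and 0 lower, also adjusted over the list alone (adjusted p = 0.885), with 1 lower without clone 7. Counts were 0 and 0, also adjusted over the list alone, for mesoderm (Eomes 0.21; adjusted p = 0.941), trophectoderm (Cdh3 −0.70; adjusted p = 0.941), 2-cell-like (Zfp352 0.36; adjusted p = 0.885) and macrophage genes (Laptm5 0.58; adjusted p = 0.941). Sex-linked genes had 0 and 0, and 0 and 3 adjusted over the list alone (Eif2s3y −2.55, SE 0.891, adjusted p = 0.164; adjusted p = 0.241 for the list). For those lists, 1 trophectoderm gene was lower without clone 10 or 7, 1 macrophage gene higher without clone 6 and 1 lower without clone 10, and 1 sex-linked gene higher without clone 10 with 2 lower without clone 10 or 6. The primed, epithelial, other imprinted, neuroectoderm, mesoderm, trophectoderm, germ line, macrophage, endothelial and strain lists differed in sign between median, mean and test.

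In all, 1010 genes (5.1%) passed between iPS and ES, 257 higher (25.4% of them) and 753 lower, and 178 changed at least 2-fold (36 higher, 142 lower). After quantile normalization 416 were higher and 788 lower (34.6% higher). The arrays did not overlap for 21.2% of genes, where 10% would be expected by chance if both groups had the same spread. The median SD was 0.0622 in ES and 0.183 in iPS, and unequal spreads raise the share expected by chance. The excess over 10% is therefore in part due to the unequal spread. The count of 1010 genes rests on the spread shared by all groups. With the spread of the clones alone, a fit in limma chosen after the data were seen, 0 genes passed (1324 at unadjusted p under 0.05, lowest adjusted p = 0.386). It fell to 415, 357 and 365 without ES 4, 5 and 6 and to 669 without MEF 2, and rose to 3917 without clone 7, which kept all 1010 in the same direction. Of the 27 lists 4 passed against other genes and 0 with an estimated correlation. By fry, which makes no comparison with other genes, the EMT (adjusted p = 0.000488), fibroblast (0.00512), reported miR-302 target (0.00512) and germ line (0.033) lists were lower on balance in iPS. The pluripotency and glycolysis lists did not pass by fry.

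ES cells, like the clones, differed from MEF in pluripotency, epithelial, fibroblast and Hox genes. The genes with the largest rises were Zfp980 (7.12), Nr0b1 (6.97, SE 0.158, adjusted p = 4.47e-09), Zfp640 (6.78), Apela (6.75), Pou5f1 (6.42, SE 0.192, adjusted p = 1.51e-08), Tdgf1 (6.36), Dppa5a (6.16), Utf1 (5.93), Bex1 (5.90) and Fbxo15 (5.87). Ankrd1 (−5.40, SE 0.0949, adjusted p = 2.46e-09), P2ry10b (−5.08), Actg2 (−4.68), Lce1h (−4.62), Tgfb3 (−4.59), Cavin2 (−4.56), Pla2g4a (−4.35), the elastic fibre gene Fbln5 (−4.31), Anxa3 (−4.26) and the desaturase gene Fads3 (−4.23) fell most. Pluripotency genes were higher in 35 of 37 and lower in 0 (Sox2 5.75, Nanog 5.60; adjusted p = 5.15e-24), cell cycle genes in 27 and 0 of 29 (Mycn 3.92; adjusted p = 3.68e-16; adjusted p = 0.0852 with an estimated correlation) and germ line genes in 14 and 0 of 17 (Tdrd12 4.26, Mael 4.22; adjusted p = 3.12e-07). Epithelial genes were higher in 19 of 23 and lower in 0 (Cdh1 5.21, Epcam 4.43, Esrp1 4.35; adjusted p = 6.27e-10; adjusted p = 0.0994 with an estimated correlation). Lower were 36 of 36 fibroblast genes (Tagln −3.55, Ccn1 −3.48; adjusted p = 4.49e-20; adjusted p = 0.0523 with an estimated correlation), 14 of 15 EMT genes (Snai2 −2.82, Zeb2 −2.69; adjusted p = 7.41e-10) and 29 of 33 Hox genes (Hoxc8 −2.90; adjusted p = 1.57e-12; adjusted p = 0.0994 with an estimated correlation), with 0 higher in each. DNA methylation and Polycomb genes had 18 higher (Dnmt3l 4.97, Tet1 4.81) and 2 lower, Mbd2 and Tet3, both chosen after their values were seen (adjusted p = 4.01e-08). Adjusted over the list alone, all these counts were the same.

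Other lists between ES and MEF were smaller or mixed. Members named here only to complete a count were chosen after their values were seen (Wee1, Kdm1a, Slain1, Lefty1, Slc38a4, Peg10, Usp29, Sesn1, Gadd45a, Tubb3, Zic1, Aldoa, Pgk1 and Pkm). Primed genes had 11 higher (Otx2 3.18, Nodal 2.98) and Fst lower (2 lower without clone 6; adjusted p = 6.7e-05; adjusted p = 0.0852 with an estimated correlation). Reported miR-302 targets had 5 higher (Lefty2 2.95, Lefty1, Slain1, Wee1 and Kdm1a) and 12 lower (Lats2 −3.18, Irf2 −2.76, Casp8 −2.65), with 6 and 12 adjusted over the list alone (adjusted p = 0.032; adjusted p = 0.0994 with an estimated correlation). Strain markers had 0 higher and 4 lower (Nnt −1.61, Ifi202b −1.21, Wdfy1 −0.74 and Entpd4 −0.62; adjusted p = 0.0213; adjusted p = 0.0994 with an estimated correlation). The microRNA locus had Larp7 higher (0.75) and 0 lower, with Mir302a at 0.12, Mir302c at 0.07, Mir302d at 0.05, Mir367 at 0.04 and Mir302b at 0.04 (list adjusted p = 0.505). The Dlk1-Dio3 region had Dio3 higher (0.48, adjusted p = 0.00833) and Dlk1 lower (−2.44; adjusted p = 0.623; 2 lower without clone 7). The list of other imprinted genes, with Nckap1 in place of H19, had 5 higher (Phlda2 5.14, Mest 2.49, Slc38a4, Peg10 and Usp29) and 13 lower, such as Ndn (−2.64), with an adjusted p = 0.21 for the list. Senescence genes had 2 higher (Sesn1 and Gadd45a; 4 without clone 7 or 10) and 9 lower, such as Plk2 (−2.18; adjusted p = 0.18). The glycolysis list, with Pigq in place of Gpi1, had 8 higher (Slc2a3 4.49) and 3 lower (Aldoa, Pgk1 and Pkm), with 7 lower without clone 7 and an adjusted p = 0.18. Neuroectoderm had 3 higher (Neurod1 3.25, Pax6 2.34 and Tubb3) and 3 lower (Nes −3.26, Map2 −2.05 and Zic1; adjusted p = 0.998).

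Lineage and cell type lists did not pass against other genes between ES and MEF. Mesoderm had Eomes higher (0.45, adjusted p = 0.0243; 0 higher without ES 4, ES 6 or MEF 1, with an adjusted p = 0.058 without ES 4) and Gata2 (−0.75), Foxf1 (−0.52), Hand2 (−0.46) and Kdr lower (adjusted p = 0.623). Endoderm had Lama1 higher (1.77; 2 higher without clone 7) and Dab2 (−2.71), Col4a1 (−1.56), Cubn (−1.05) and Pdgfra lower (adjusted p = 0.554). Trophectoderm had Tfap2c higher (2.65; 2 higher without clone 10) and Gata3 (−0.99) and Krt7 (−0.69) lower (adjusted p = 0.623). The 2-cell-like list had Tdpoz3 (1.15), Pramel7 (0.38, adjusted p = 0.0386) and Tcstv3 (0.37, adjusted p = 0.0341) higher and 0 lower (adjusted p = 0.18; 1 higher without ES 4, 5 or 6 or MEF 1 or 3, with an adjusted p = 0.116 for Pramel7 and 0.0861 for Tcstv3 without ES 4). Interferon genes had Oas1a higher and 7 lower, such as B2m (−2.07) and Ifi35 (−1.41; adjusted p = 0.437), with 0 higher without ES 4, 5 or 6 or MEF 2 and 4 without clone 7. Macrophage genes had Laptm5 (3.10) and Cd68 (1.46) higher and Lyz2 (−0.97), Cd14 (−0.81) and Csf1r lower (2 and 2 adjusted over the list alone; adjusted p = 0.998). Endothelial genes had Esam (1.09), Tek (0.77), Robo4 (0.65) and Vwf higher and Flt1 (−2.70) and Emcn lower (adjusted p = 0.461). Muscle genes had 0 higher and Des (−0.71, adjusted p = 0.026; adjusted p = 0.0655 without ES 4), Tnnc1 (−0.68), Tnnt2 (−0.55) and Chrna1 (−0.41) lower (adjusted p = 0.461). Keratinocyte genes had Sfn (2.37) and Krt17 (1.79) higher and Perp (−1.15) lower (adjusted p = 0.553). Sex-linked genes had Xist lower (−3.22) and 0 higher (adjusted p = 0.623), with 1 higher without clone 6 and 2 higher and 2 lower without clone 10. Outside the targets and macrophage genes, the counts of the last 2 paragraphs were the same adjusted over the list alone. The neuroectoderm, mesoderm, endoderm and sex-linked lists differed in sign between median, mean and test. Kdr, Pdgfra, Csf1r, Oas1a, Vwf and Emcn were chosen after their values were seen.

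In all, 8271 genes (41.5%) passed between ES and MEF, 3911 higher and 4360 lower, and 3569 changed at least 2-fold (1584 higher, 1985 lower). With the spread of the clones alone 4425 passed, but the clones are in neither group here, so that count does not measure the uncertainty of this comparison. With array weights, whose estimate did not converge, 13572 passed. The arrays did not overlap for 59.2% of genes, where 10% would be expected by chance if both groups had the same spread. Of the 27 lists 11 passed against other genes and 4 with an estimated correlation. Genes past the test in 1 comparison and not in another were not tested for a difference between the comparisons.

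Taken over all genes, the clones lay close to ES cells on the path from MEF, with Nr0b1, Pou5f1 and Sox2 changed by like amounts in both and Lox by more in iPS. Projected on the line from the MEF mean to the ES mean, clones 6, 7 and 10 had covered 91.5%, 97.3% and 97%. The projection leaves out differences off that line. The root mean square log2 difference from the single ES arrays averaged 0.343, 0.454 and 0.341 in turn, so clone 7 was the farthest from ES. For an ES array against the others it was 0.112 to 0.124. Their correlations with the single ES arrays averaged 0.985, 0.973 and 0.985, and those with the single MEF arrays 0.894, 0.874 and 0.883. The changes of iPS and of ES from MEF correlated at r = 0.952 across 19934 genes, with a covariance of 0.792. Simulated unchanged groups sharing the MEF arrays gave 0.327 (highest 0.347), with a covariance of 0.0056. Those groups do not differ from MEF at all, so their values show only what sharing the arrays adds. They do not measure how close the clones lay to ES. Both comparisons called 3114 genes higher and 3980 lower, calls that the shared MEF arrays favour, and 26 genes passed in opposite directions.

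**Figure D1:**
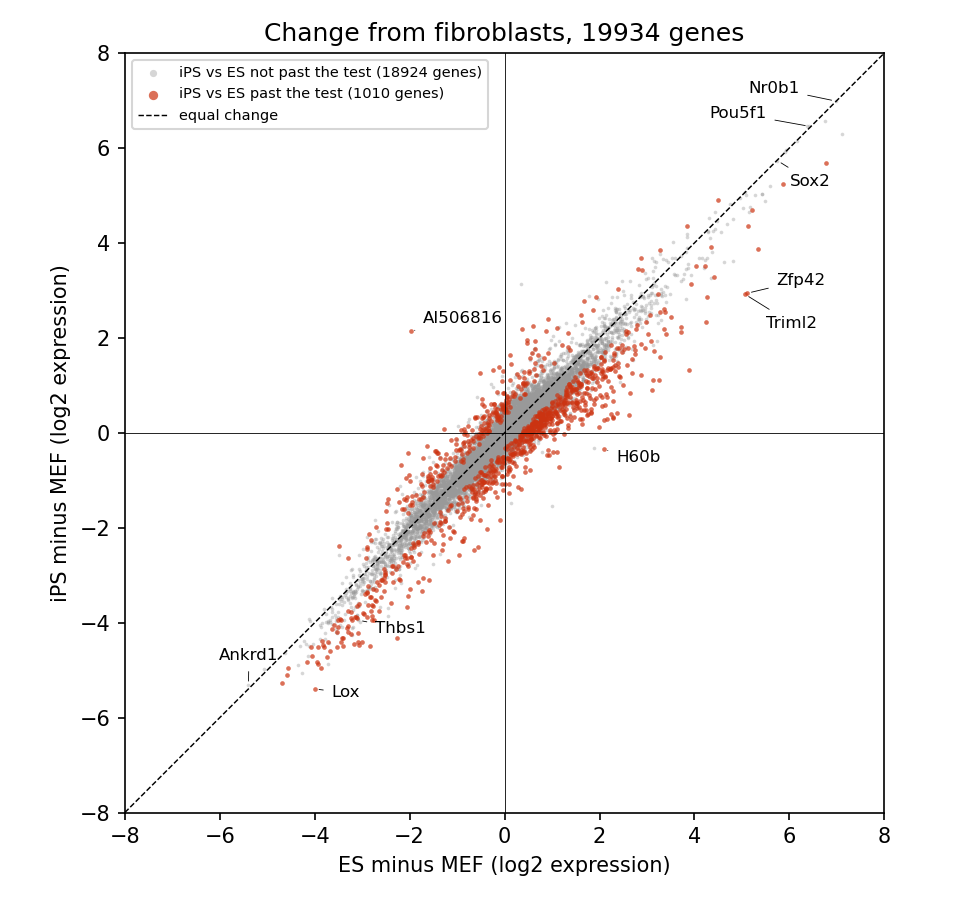
Changes from MEF of 19934 genes. The x axis is the ES minus MEF and the y axis the iPS minus MEF difference of group means (log2, n = 3 arrays per group). Red points are the 1010 genes past the test between iPS and ES, grey the other genes, and the dashed line marks equal change; r = 0.952. Labelled are Nr0b1, Pou5f1, Sox2, Zfp42, Triml2, H60b, Thbs1, Lox, Ankrd1 and AI506816, the last chosen after its value was seen.

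Genes such as Zfp42 and Neurod1 read between MEF and ES in iPS, while Lox and Cav1 read lower than in both. Feeder RNA in the ES arrays, which stays open below, would raise the ES level of fibroblast genes, so Lox and Cav1 need not have passed it. Of the 1010 genes that differed between iPS and ES, 856 also differed between ES and MEF. In 593 of them iPS lay on the MEF side of ES (144 higher and 449 lower than ES), and in 263 on the far side (43 higher, 220 lower). Both comparisons use the same ES arrays, whose own deviations push calls to the MEF side, so neither independent lists nor simulations of unchanged groups give a fitting value for no effect. The MEF side count was 252, 212 and 218 without ES 4, 5 and 6, 378 without MEF 2 and 1802 without clone 7, and the far side count 94, 87 and 89 without ES 4, 5 and 6, 514 without clone 6 and 975 without clone 7. MEF and iPS carry the same strain label and ES another, so a strain difference alone can put a gene on the MEF side. The labels do not separate this from cell origin. Of 5 strain markers 4 differed between iPS and MEF and 1 between iPS and ES, so the markers did not follow the labels. What strain adds to these counts is open.

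**Figure D2:**
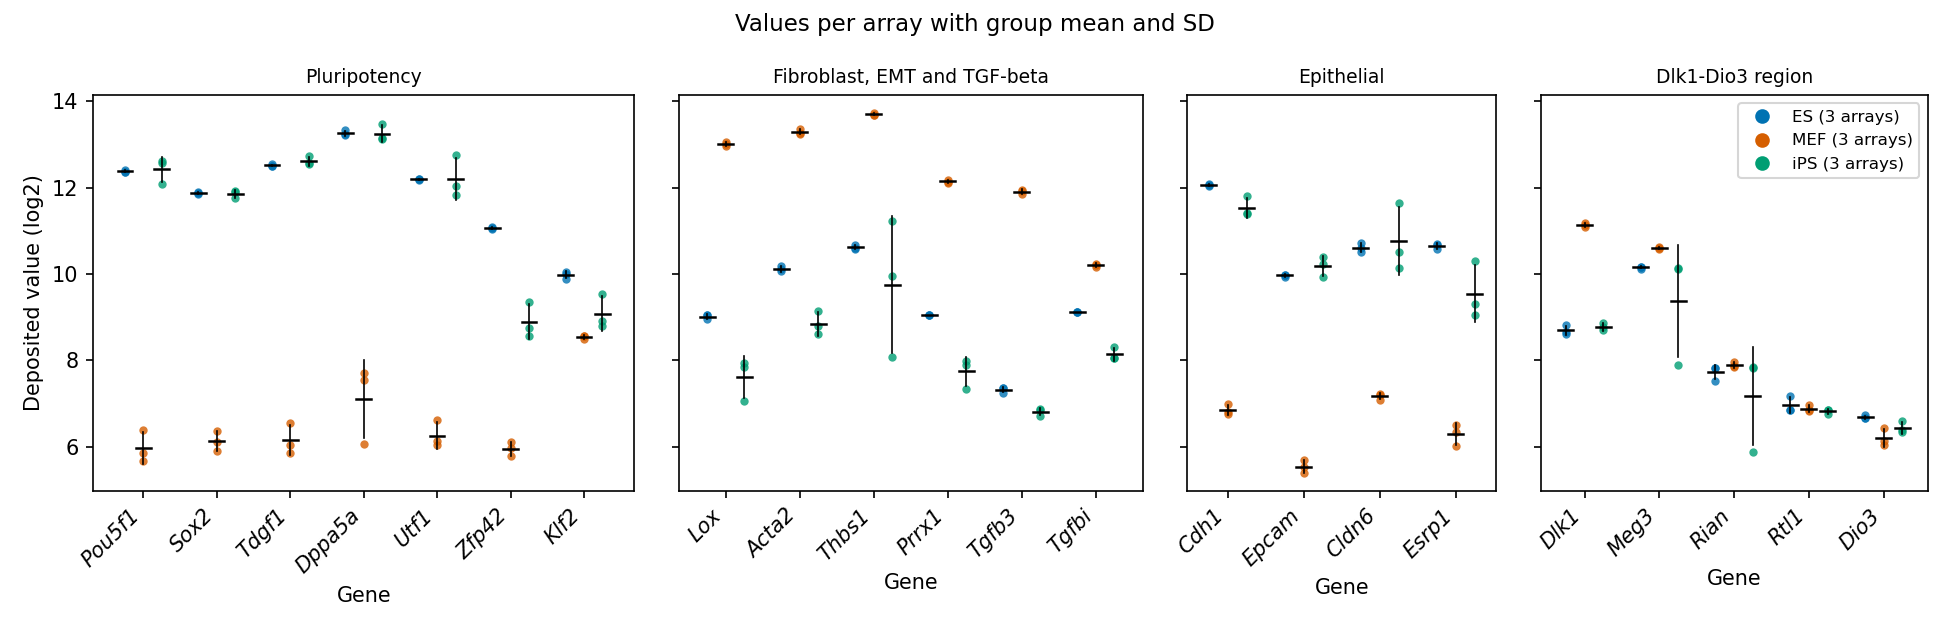
Deposited log2 values per array of named genes in 4 panels (pluripotency, fibroblast with EMT and TGF-beta, epithelial, Dlk1-Dio3). The y axis is the log2 value, groups on the x axis are ES, MEF and iPS with n = 3 arrays each, points are single arrays and bars show the group mean and SD. Means in ES, MEF and iPS were 12.39, 5.97 and 12.42 for Pou5f1, 9.01, 13.01 and 7.61 for Lox, 12.06, 6.85 and 11.54 for Cdh1, and 10.15, 10.60 and 9.38 for Meg3.

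The clones varied more among themselves than the arrays of the other groups. They are separate clones, while the labels do not state whether the ES and MEF arrays came from separate cultures, so the spreads may differ in kind. Meg3 and Rian are non-coding RNAs of the imprinted Dlk1-Dio3 region, which also holds a large cluster of microRNAs and small nucleolar RNAs. In clone 7 these features were low: Meg3 stood 2.25, Rian 1.97 and Mir380 1.90 log2 units below the mean of the other clones. These features were examined after the values were seen. Of 45 non-coding features in the region 40 were lower in clone 7 and 11 at least 2-fold lower, with a median of −0.46, while medians in clones 6 and 10 were 0.24 and 0.209 with 0 features at least 2-fold lower. The protein-coding Dlk1, Rtl1 and Dio3 deviated by −0.01, −0.09 and −0.09 in clone 7, and 10 flanking genes by a median of −0.049. The median SD over genes was 0.0622 in ES, 0.0943 in MEF and 0.183 in iPS. Genes at least 2-fold from the mean of the other arrays of the group numbered 245, 926 and 151 in clones 6, 7 and 10, and 0 to 4 in the ES and MEF arrays. Correlations between arrays were 0.998 to 0.9986 in ES, 0.9945 to 0.9982 in MEF and 0.9675 to 0.9888 in iPS.

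**Figure D3:**
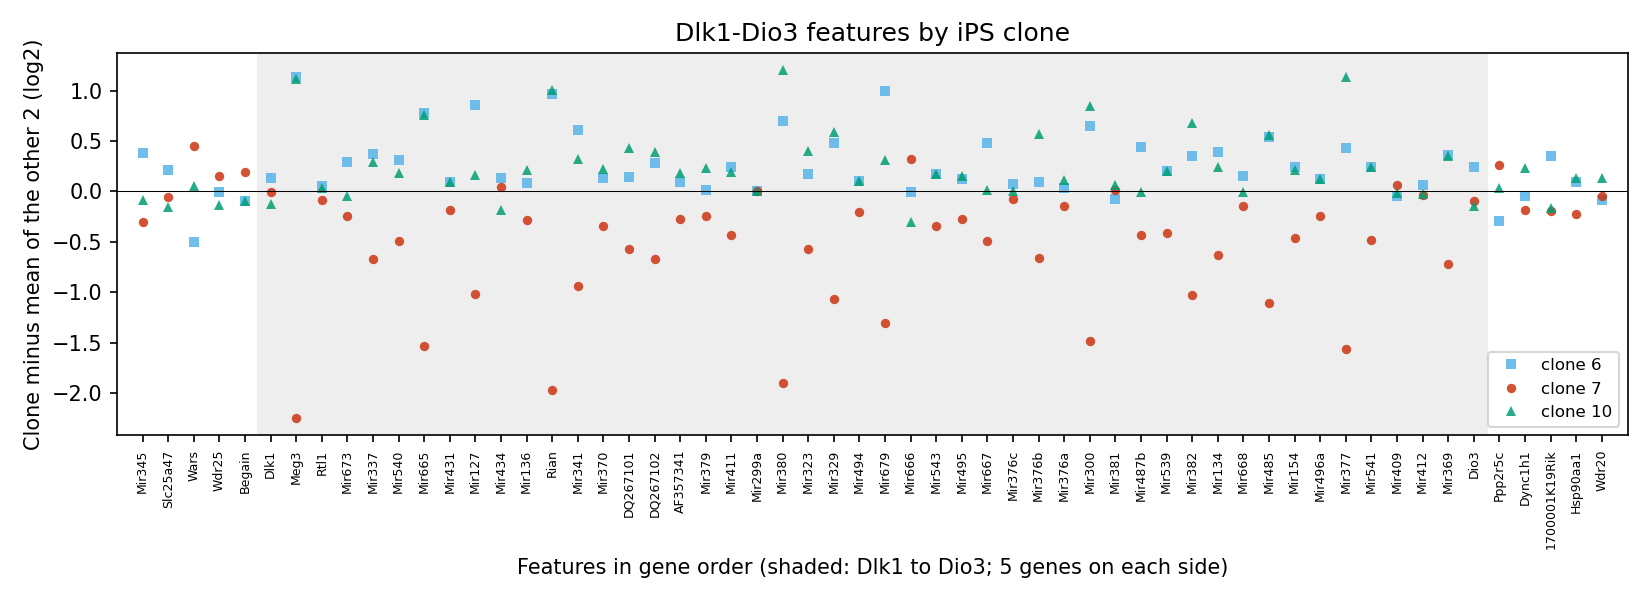
Features of the Dlk1-Dio3 region and 5 flanking genes on each side. The y axis is the value of each clone minus the mean of the other clones (log2), the x axis the order along the chromosome, and the shading runs from Dlk1 to Dio3; n = 1 array per clone. The medians over 45 non-coding features were 0.24 in clone 6, −0.46 in clone 7 and 0.209 in clone 10.

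Chromosome 8, where Zfp42 and Triml2 lie, was examined after the values were seen. Its 498 genes with a mean of at least log2 8 stood 0.137 above other autosomes in ES relative to the other arrays, 0.12 against MEF and 0.144 against iPS. An exact permutation test of 3 ES arrays against the 6 others gave p = 0.0238, the smallest it can give, and an adjusted p = 0.226 over chromosomes. Chromosome 4 gave the same values in that test, with ES lower by a smaller amount (−0.018). On this chromosome 85 of 961 genes (8.84%) were lower in iPS than ES, against 639 of 18201 (3.51%) on other autosomes (Fisher exact p = 2.11e-13, odds ratio 2.67), a test that treats neighbouring genes as independent.

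**Figure D4:**
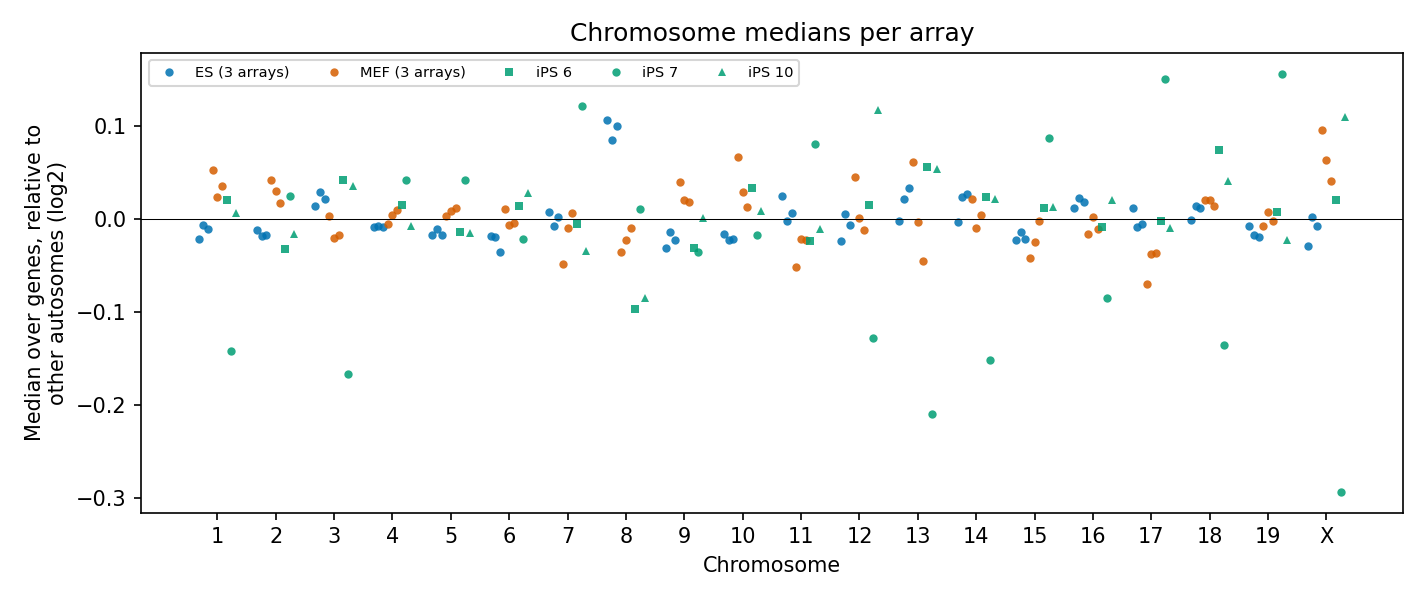
Median over genes of each chromosome relative to the other autosomes. The y axis is the log2 difference, the x axis chromosomes 1 to 19 and X, and each point is 1 of 9 arrays coloured by group (ES, MEF, iPS; n = 3 each). ES arrays stood between 0.085 and 0.106 on chromosome 8.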

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

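The comparison of iPS with ES depended most on the settings, that of iPS or ES with MEF least. Of the named genes and comparisons in all settings, 7083 kept their call, 323 became weaker, 127 stronger and 0 reversed. Among the 20 largest changes between iPS and ES, 17 to 20 passed in each setting but 1, the spread of the clones alone, where 0 passed.

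No paired analysis was possible because the labels pair no arrays between groups. The number 6 common to ES and iPS is an array number in ES and a clone number in iPS, so it makes no pair. Adding 1 or 16 to linear values before taking logarithms was not run, since the values were already on a log scale. Where leaving out an array left a group with 2, the pooled spread was used.

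Quantile normalization again gave 6 pluripotency genes lower and 1 epithelial gene higher in iPS than ES, and a spread within ES of 0.055. Leaving out the dimmest genes raised the spread within iPS to 0.228. Counting every probe set gave 332 past the test and 2-fold between iPS and ES. With only the 2 groups compared, 465 genes passed between iPS and ES, 299 on the MEF side and 133 on the far side, with 1 epithelial gene lower. An intensity trend with robust moderation left 2 epithelial genes lower.

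Array weights raised the count between iPS and ES to 4149 (273 at least 2-fold) and that between ES and MEF to 13572. The MEF side then held 2033 and the far side 1416 genes, with 1 pluripotency gene higher and 11 lower, and 1 fibroblast, 1 EMT and 2 epithelial genes higher in iPS than ES. The estimate of those weights did not converge, and MEF 2 received a weight of 38.46 against 0.069 for clone 7, so these counts lean on few arrays. Without moderation 657 genes passed between iPS and ES, 387 of them on the MEF side, with 2 epithelial genes lower, and 0 epithelial genes were lower in iPS than MEF.

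A 2-fold minimum left 3416 genes between iPS and MEF, 178 between iPS and ES and 3569 between ES and MEF, with 98 on the MEF side and 31 on the far side. Lower in iPS than ES were then 1 pluripotency, 7 fibroblast, 0 EMT and 0 epithelial genes, and 0 epithelial genes were lower in iPS than MEF. At an adjusted p under 0.01, 384 genes passed between iPS and ES, 222 on the MEF side and 93 on the far side. Lower in iPS than ES were then 1 pluripotency, 3 EMT and 2 epithelial genes, with 0 epithelial genes lower in iPS than MEF.

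Chosen after seeing the data, the spread of the clones alone gave 4020 genes between iPS and MEF. It gave 4425 between ES and MEF, where the clones are in neither group. Between iPS and ES it gave 0, so 0 were 2-fold, 0 on the MEF side and 0 on the far side. In that fit 0 pluripotency, 0 fibroblast, 0 EMT and 0 epithelial genes were lower in iPS than ES, and 0 epithelial genes lower in iPS than MEF. With 1 array weight per group, also chosen after seeing the data, 693 genes passed between iPS and ES and 382 lay on the MEF side.

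With an estimated correlation in camera, the epithelial list had an adjusted p = 0.108 between iPS and MEF, and between iPS and ES the pluripotency list had an adjusted p = 0.884, the fibroblast list an adjusted p = 0.272 and the EMT list an adjusted p = 0.0915. By fry the pluripotency list had an adjusted p = 0.204.

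Leaving out each array in turn gave 357 to 3917 genes between iPS and ES, lowest without ES 5 and highest without clone 7, with 121 (without ES 6) to 283 (without clone 6) at least 2-fold. The MEF side then held 212 to 1802 and the far side 87 to 975 genes. Pluripotency genes higher in iPS than ES numbered 0 to 2 and lower 1 to 11, fibroblast genes higher 0 to 2, EMT genes higher 0 to 1 and lower 2 to 9, and epithelial genes higher 0 to 2 and lower 1 to 5. Epithelial genes lower in iPS than MEF numbered 0 to 1. The share of higher genes among those past the test between iPS and ES was 25.4%, and 34.6% after quantile normalization, 38.2% with every probe set, 39.9% with array weights and 36.4% without clone 7.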

Other observations

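Zfp42 is a naive pluripotency marker, and Triml1 and Triml2 are its neighbours on chromosome 8. All 3 were lower in iPS than ES (−2.17, −1.58 and −2.15 log2), Triml1 with an adjusted p = 0.000805, while the nearby Frg1 stood at −0.16 (adjusted p = 0.722). The 3 clones each held Zfp42 between 8.58 and 9.35. Triml1 and Frg1 were chosen after their values were seen.

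Atf4 drives the response to amino acid shortage, Asns makes asparagine, Cars charges a transfer RNA and Slc7a2 imports arginine. These genes, chosen after their values were seen, were among the 26 that passed in opposite directions from MEF: higher in iPS (Slc7a2 0.60, Atf4 0.46, Asns 0.43, Cars 0.40) and lower in ES (−0.47, −0.37, −0.25 and −0.27). They are 4 of 10 genes with that pattern, and no list of such genes was tested. Tmem64 (−0.72 and 1.15) and Atp10d (−1.19 and 0.34) went the other way, and AI506816 was 4.12 higher in iPS than ES.

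For the Dlk1-Dio3 features low in clone 7, both tests were chosen only after the result was seen, and the outcome expected for the random lists was written down after theirs was seen. The median of 45 non-coding features, −0.46, was reached by a share of 0.0001 of matched random lists, the smallest they can give, which argues against a deviation of the whole array. The random lists treat neighbouring features as independent. A lower signal of all microRNA features may add to it, yet 251 such features elsewhere had a median of −0.142 against −0.433 for 40 inside the region, narrowly under the 1 in 3 set beforehand as a sign of it. Loss of imprinting is a candidate explanation that stays open, as no methylation was measured and the clone has 1 array.

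For chromosome 8 in ES, the tests were chosen only after the result was seen, and the outcomes expected for few genes and for level bias were written down after theirs were seen. A few strongly changed genes would leave about 50% above the median of other autosomes, but 63.9% of 498 genes (95% interval 59.5% to 68%) lay above it. That share argues against them as the whole cause, but the lower bound missed the 60% written down, so the rule set left it undecided. A local stretch is argued against by the lowest of 5 block medians, 0.096, and a level-dependent bias by a share of 0.0001 of matched random lists, the smallest they can give. The interval and the random lists treat neighbouring genes as independent. The lists address only bias by level, and other differences between arrays were not tested. An extra chromosome copy in some ES cells, or strain, may explain it and stays open, since neither was tested (exact permutation p = 0.0238 and adjusted p = 0.226 for the arrays). Larger shifts arose on other chromosomes in the single array of clone 7, which stood at −0.21 on chromosome 13, 0.156 on 19 and 0.15 on 17. The ES arrays stood between 0.085 and 0.106 on chromosome 8.

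For fibroblast genes higher in ES than iPS, the tests were chosen only after the result was seen, that of all genes far higher in MEF after the other feeder tests, and the outcome expected for Hox genes after theirs was seen. Feeder fibroblasts carried into the ES arrays are a candidate explanation. The treatment note's step that would remove them covers ES by listing order, the likelier numbering, but the labels do not state the numbering. The 18 list genes at least 8-fold higher in MEF than iPS, a choice that favours shares above 0, implied 1.55% to 12.2% MEF RNA (median 5.58%). Their upper to lower quartile ratio was 2.14, which leaves carry-over undecided. Of 66 genes at least 16-fold higher in MEF than iPS, 3% implied a share of 0 or less (median 3.06%), as carry-over may give, but their selection used the iPS arrays. The 7 Hox genes at least 4-fold higher in MEF than iPS, 5 of them higher in ES than iPS, had a median ES minus iPS of 0.165 (95% interval −0.041 to 0.312), an interval that holds both 0 and the 0.281 predicted. Strain and true expression in ES may also contribute and stay open: the list's most abundant genes in MEF stood at 13.70 in MEF, 10.62 in ES and 9.75 in iPS (Thbs1) and at 13.53, 12.90 and 12.69 (Vim), iPS means of 22 of its 36 genes were at least log2 8, and other lists hold 2 of them (Pdgfra and Dcn).

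For the number of genes past the test, the tests on regrouped arrays were chosen only after the result was seen. The 10 splits of the arrays of a pair of groups are too few for a share under 0.05. In each comparison 1 of the splits gave as many genes, the real one, with 8488 between iPS and MEF, 1010 between iPS and ES and 8271 between ES and MEF. The highest of the other splits gave 0. Those splits mix arrays of both groups, so any real difference enters their spread and few calls could arise. The 0 therefore does not measure what chance would give.

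Clone 10 read low for the Y-linked Eif2s3y (5.03), Uty (5.24) and Kdm5d (5.87), against 9.48, 9.28 and 7.81 in clone 6 and 8.39, 8.43 and 8.01 in clone 7. The 256 X-linked genes stood 0.234 higher in clone 10 than in clone 6, where autosomes ranged from 0.045 to 0.163, and stood at −0.136 in clone 7 against clone 6, where autosomes ranged from −0.052 to 0.347. MEF held both Xist (mean 11.31) and the Y-linked Eif2s3y (9.18) and Uty (7.96). Nnt, a strain marker, stood at 9.11 in ES, 10.72 in MEF and 9.71 in iPS, so it read higher in both groups labelled C57BL/6J, a strain known for a deletion in this gene, and the part of the gene the probe set reads was not examined.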
